A study of Mus musculus with 12 samples.

How the data were processed

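RNA-seq was made from embryonic gut of C57BL/6J mice, wild type or homozygous for a null allele of Ret, the receptor tyrosine kinase that carries the GDNF signal in the enteric nervous system. Guts were taken at embryonic day 11.5 (E11.5) and 12.5 (E12.5), with 3 libraries per genotype and age and 12 libraries in all. Per the labels' protocols, RNA was extracted by a combined Trizol and RNeasy column method, polyadenylated RNA was selected with oligo-dT beads, libraries were made with the Illumina TruSeq kit and read as 75 bp pairs on a HiSeq 2000. Picard, TopHat2, Cufflinks and Cuffdiff and the genome build mm10 are named per the submitters' processing notes, and their versions, settings and the annotation are not given in the sources used here.

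One table per age was used. Per the file headers, each gives 1 value per genotype and gene. As the processing notes name Cuffdiff, these values were read as FPKM (fragments scaled by transcript length and by all mapped fragments). They were taken as made by the authors from the 3 libraries of that genotype. Per the file headers, the deposited tables also hold a log2 fold change of null over wild type, a test statistic (a score), a p-value and a q-value per gene. Values per library were not used here, so no SD, no n and no leave-one-out value stand beside an FPKM, and the depth of the libraries is unknown. A p-value of these tables measures the spread between libraries as Cuffdiff modelled it, and the labels do not say whether a library came from 1 embryo or from several. FPKM is a relative measure: tissue carried into a dissection changes the level of every gene that it expresses, and lowers the share left for the others. The 2 ages were scaled in separate tables, so levels of the 2 ages are set side by side as values, and only folds and calls, each made within a table, were tested across ages. The E12.5 table names its columns wt and null, while the E11.5 table names them w and h, and h was read as the homozygous null, with the lower level of Ret.

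The E11.5 table has 23234 rows, of which 1 was shifted by several columns and left out, and 13430 genes were tested by the authors. The E12.5 table has 23235 rows and 13783 tested genes. Each table has 1 gene that Cuffdiff set aside for too many fragments. FPKM summed over all rows came to 507453 in wild type and 526130 in null at E11.5, and to 552491 and 479009 at E12.5. The median log2 fold change of genes at an FPKM of 1 or more was 0.01 at E11.5 and 0.0013 at E12.5.

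No test of library values could be made, so the main result is the one set out for this case before the data were examined: a gene was called at a q-value under 0.05 in the authors' deposited table. Fold changes were computed again from the FPKM as log2(null / wild type) with no pseudocount. A gene listed at 0 in 1 genotype gets no fold, and was ranked with a pseudocount of 0.1. The smallest p-value in both deposited tables is 5e-05, which many genes share.

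Rows were checked for cells that follow from one another, with 1 rule for both tables, chosen after the data were examined. A row was marked when an FPKM, fold or statistic had more than 6 significant digits, when the listed fold differed from the FPKM ratio by more than 0.001, when the fold and the statistic had opposite signs, when the q-value lay more than 25% from the Benjamini-Hochberg value of the p-values, or when p was 0.001 or less with a statistic under 80% of the smallest one at such p in the E11.5 table. The rule marked 1 row at E11.5 (Foxp4) and 158 rows at E12.5, of which 151 were called. It was revised after it was seen which rows it took. The first form also marked rows at p of 0.1 or more with a statistic above 2.5, which took rows such as those of Sftpc and Myl2, and set the lower limit near the smallest E11.5 statistic rather than at 80% of it; a form with the lower limit at 100% marked 168 E12.5 rows, 161 of them called. Marking rows whose statistic recurs in more than 3 rows was left out, as it would add 1 row, that of Ret. Results under each of these forms, and with no limit on the statistic, were computed. E12.5 totals, and counts of the neural, network, Hirschsprung and mesenchyme lists, are given with and without the marked rows, with p-values adjusted again over the rest.

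Gene lists, 31 in number, were written before the data were examined. They cover the enteric lineage, other gut cell types, neighbouring organs, blood and vessels, signalling pathways, Hox genes, cell cycle, sex-linked and handling-related genes. For each list and age, called members were counted, over-representation was tested with Fisher's exact test (two-sided, against all other tested genes, Benjamini-Hochberg adjusted over the 31 lists for each direction), and the percentile of the median log2 fold change among 10000 random lists matched on mean FPKM was taken. These tests treat genes as independent, which they are not, and describe these tables. Overlap of calls between ages was tested with Fisher's exact test per direction. Further marker genes of skeletal muscle, liver, heart and neurons, none in a list, were written down after the list results were seen and before their own medians were computed, and used to test explanations.

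The test of the difference between ages was meant to use standard errors from the test statistic. The statistic is not on a normal scale: at a statistic near 1 the median deposited p-value was 0.098 at E11.5 and 0.084 at E12.5. A substitute chosen after the data were examined took the standard error as the log2 fold divided by the normal deviate of the deposited p-value, raised where needed to the median of its FPKM decile. It used unmarked rows, was two-sided and was Benjamini-Hochberg adjusted. Where p is at its floor of 5e-05, this standard error is too large, which caps the test, so that its smallest p-values tend to fall on genes at the floor at both ages with opposite folds of similar size. On simulated data with 200 changed genes among 12866, this test recovered 39.2% of genes changed by 1 on the log2 scale and 72.4% of those changed by 2, and 7 unchanged genes were called. The simulation drew normal noise from the same standard errors that the test assumes. It therefore does not show how the test behaves on the authors' p-values.

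Genes named in the text follow a rule written before the data were examined: Ret and the RET-EDNRB network, the 12 called genes with the largest fall and the 12 with the largest rise at each age at an FPKM of at least 1, up to 4 called members per list (or up to 2 of the highest mean FPKM where none was called), up to 6 genes called in the same direction at both ages, and up to 6 with the smallest p of the difference between ages. Outside this rule, Chga, Foxp4, Hand2, Hbb-y, Isl1, Lhx3, Myl2, Neurog1, Neurog2, Olig2, Pdgfra, Penk, Sftpc, Sox1 and Tagln3 were chosen after their values were seen. Gene coordinates are those of GENCODE M21 on GRCm38, the assembly called mm10. Strand settings were not stated, so reads of overlapping genes on opposite strands may be shared, and members of gene families such as Serpina1 and the globins are uncertain. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were other q thresholds (0.01 and 0.1), an FPKM minimum of 1, a fold limit of 1 on the log2 scale, pseudocounts of 0.1 and 1, recentring on the median fold, lists without shared genes, and the other marking rules.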

Results

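Gene expression was measured by RNA-seq in mouse gut at 2 ages of development, E11.5 and E12.5, in wild-type embryos and in embryos lacking Ret, with 3 libraries in each of the 4 groups. Neural crest cells that need RET colonise the gut over these days, and the comparison asks which genes differ in the gut when the receptor is missing. Each FPKM below is the authors' value for a genotype, given without a spread between libraries, and the depth behind it is unknown.

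Ret, at chromosome 6 from 118151745 to 118197718 on the minus strand (GRCm38, protein coding), was lower in the null at both ages. At E11.5 it stood at 8.80 FPKM in wild type and 0.0354 FPKM in null, a log2 fold change of −7.96 with q = 0.0042 in the authors' deposited table. At E12.5 it stood at 9.91 and 2.57 FPKM, a log2 fold change of −1.95 with q = 0.0019 in the authors' deposited table. The test statistic of the E12.5 row of Ret, −4.89, recurs in 19 rows of that table, 18 of them rows whose cells do not follow from one another, while the other cells of the Ret row do follow from one another. The null level was 0.402% of wild type at E11.5 and 25.9% at E12.5. The size of the E11.5 fold rests on a very low null value: at a pseudocount of 1 the log2 fold changes were −3.24 at E11.5 and −1.61 at E12.5. Whether the remaining Ret at E12.5 lay in all 3 null libraries or in 1 of them is unknown without values per library, so the genotype label of each library could not be checked, and every E12.5 fold and call rests on those labels. The test of the difference between ages did not pass after adjustment (difference 6.01, SE 2.28, approximate adjusted p = 0.092 computed from the authors' p-values).

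At E11.5 the null libraries had lower levels of neural crest and neuronal genes and of genes of skeletal muscle, the urogenital ridge and the posterior Hox clusters. They had higher levels of epithelial, smooth muscle and liver genes. Of 13430 tested genes, 1956 were called, 764 higher and 1192 lower in the null. Among them, 258 were higher and 348 lower by at least 1 on the log2 scale. The genes with the largest falls, after Ret, included the muscle genes Myh3, Tnnc2, Chrng, Myl1 and Myog and the transcription factor genes Uncx and Tbx15, and the largest rises included Xist, Alb, Cym, Afp and Barx1.

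Genes of enteric neural crest progenitors and glia fell as a group at E11.5. Of 22 tested members, 14 were lower and 2 higher (Gfra1 and Hand2), with a median log2 fold change of −1.07 (Fisher's exact test for lower members, adjusted p = 4.42e-09; 17 adjusted over the list alone). Ret itself, whose fall follows from the genotype, is among the lower members. Sox10, which marks progenitors and glia, fell from 9.15 to 2.89 FPKM. Ednrb, the endothelin receptor gene of these progenitors, was at 18.8 FPKM in wild type and 17.5 FPKM in null, with q = 0.69 in the authors' deposited table. Neuronal genes fell likewise: of 27 tested, 22 were lower and 1 (Isl1) higher, with a median of −0.91 (Fisher's exact test, adjusted p = 9.91e-18; 23 adjusted over the list alone). Tubb3, the neuronal tubulin gene, went from 23.8 to 6.90 FPKM, Stmn3 from 6.38 to 2.34 FPKM and Elavl4 from 4.56 to 1.65 FPKM. Of 10 tested neurotransmitter and neuropeptide genes, 6 were lower and 1 (Penk) higher (Fisher's exact test, adjusted p = 0.00038; 7 adjusted over the list alone). The catecholamine genes Th and Dbh fell from 17.7 to 6.12 FPKM and from 27.2 to 9.13 FPKM, the neuropeptide gene Gal from 5.76 to 0.505 FPKM. Markers of sympathetic and spinal neural tissue moved with them: 4 of 5 tested members were lower, Th and Dbh among them (Fisher's exact test, adjusted p = 0.0011; 5 adjusted over the list alone).

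In the RET-EDNRB network, a set of ligand, receptor and transcription factor genes linked to RET and the endothelin receptor, 14 members were tested at E11.5. Some of its members may have been chosen on tissue like this, so its counts are not independent evidence. Of these, 5 were lower, Ret and Sox10 among them, and 4 were higher (9 adjusted over the list alone). The ligand gene Gdnf rose from 8.73 to 14.9 FPKM, its co-receptor gene Gfra1 from 14.9 to 28.1 FPKM, Ece1, an endothelin-converting enzyme gene, from 32.9 to 42.5 FPKM, and the transcription factor gene Nkx2-5 from 1.14 to 5.05 FPKM. Nkx2-5 is also in the cardiac muscle list. The visceral smooth muscle and gut mesenchyme lists were higher in the same libraries (medians 0.82 and 0.31). Whether these 4 rises go beyond that was not tested. Gata2 fell from 15.6 to 10.1 FPKM, and Cbl, which encodes a ubiquitin ligase acting on RET, from 7.28 to 1.72 FPKM. Among 17 tested Hirschsprung disease genes, many of them also in the network, 6 were lower, Ret among them, and 3 higher (10 adjusted over the list alone).

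Epithelial, smooth muscle and mesenchyme genes of the gut were higher in the E11.5 null. Of 23 tested gut epithelium genes, 20 were higher and 0 lower, with a median of 1.04 (Fisher's exact test, adjusted p = 4.67e-21; 22 adjusted over the list alone). The endoderm factor gene Foxa2 rose from 1.32 to 7.09 FPKM, Ihh from 2.13 to 8.29 FPKM, Foxa1 from 4.23 to 15.7 FPKM and Hnf4a from 1.99 to 6.30 FPKM. Of 16 visceral smooth muscle genes, 11 were higher and 1 (Des) lower (median 0.82; Fisher's exact test, adjusted p = 6.56e-10; 12 adjusted over the list alone), with Myh11 from 6.93 to 29.1 FPKM and Actg2 from 39.8 to 113 FPKM. Of 16 gut mesenchyme genes, 7 were higher and 1 (Twist1) lower (Fisher's exact test, adjusted p = 0.00011; 10 adjusted over the list alone). Barx1, a transcription factor gene of the stomach mesenchyme, rose from 4.46 to 109 FPKM and Foxf1 from 51.3 to 124 FPKM. Whether the 2 genotypes were sampled over the same stretch of gut was not tested. Hedgehog genes were called higher in 5 of 12 members and lower in 2 (9 adjusted over the list alone), with Shh from 8.60 to 22.5 FPKM and its target gene Gli1 from 28.5 to 51.4 FPKM. Pancreas genes were higher in 5 of 9 (Fisher's exact test, adjusted p = 0.00035; 6 adjusted over the list alone), with Gcg, the glucagon gene, higher by 1.35 on the log2 scale, and 1, Chga, was lower.

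Markers of neighbouring tissues differed between the genotypes at E11.5 beside all of these groups. All 8 tested skeletal muscle genes were lower in the null (median −3.59; Fisher's exact test, adjusted p = 2.93e-08; 8 adjusted over the list alone), with Myog, a myogenic factor gene, from 17.0 to 1.07 FPKM. Of 11 mesonephros, kidney and gonad genes, 8 were lower and 2 higher (Fisher's exact test, adjusted p = 3.03e-06; 10 adjusted over the list alone), with Pax2 from 4.50 to 0.836 FPKM and Nr5a1 from 11.1 to 3.52 FPKM. Liver genes went the other way: 13 of 15 were higher (median 3.00; Fisher's exact test, adjusted p = 8.72e-14; 13 adjusted over the list alone), with Alb, the serum albumin gene, from 0.433 to 72.8 FPKM and Afp, also expressed by early gut endoderm, from 4.68 to 148 FPKM. Of 14 posterior Hox genes, 11 were lower and 1 (Hoxd13) higher (median −0.84; Fisher's exact test, adjusted p = 7.58e-09; 12 adjusted over the list alone), with Hoxc10 from 19.4 to 5.94 FPKM, and of 14 anterior Hox genes 6 were higher and 2 lower (10 adjusted over the list alone). The genotypes also differed in sex-linked genes: Xist stood at 0.136 FPKM in wild type and 31.8 FPKM in null, and the 4 tested Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower in the null (5 adjusted over the list alone). A larger share of female embryos in the null libraries would give both, so embryo sex and genotype were not separated at E11.5.

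At E12.5 the null libraries again had lower levels of neural crest and neuronal genes. They also had lower levels of heart and lung genes, which tissue carried into the wild-type libraries may account for, as taken up below. Of 13783 tested genes, 1060 were called, 275 higher and 785 lower. Among them, 19 were higher and 404 lower by at least 1 on the log2 scale. Without the 158 marked rows, 909 were called, 263 higher and 646 lower. The largest falls included Myh6, Mybpc3, Myl3, Tbx4, Myh7 and Tbx20. The largest rises were smaller, and 3 of them, none of which is in a list, were BC021767 from 0.221 to 2.06 FPKM, A530016L24Rik from 0.206 to 1.49 FPKM and Rab11fip5 from 8.55 to 42.2 FPKM.

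Enteric neural crest genes were lower in 13 of 21 tested members at E12.5 and higher in 1, Gfra1 (median −0.94; Fisher's exact test, adjusted p = 1.23e-10; 16 adjusted over the list alone). Of the 21 members, 9 lie in marked rows, and without them 5 of 12 were lower and 1 higher (median −0.75; Fisher's exact test, adjusted p = 0.000545). Ret itself, whose fall follows from the genotype, is among the lower members with and without the marked rows. Gfra2, the neurturin co-receptor gene, fell from 7.29 to 3.80 FPKM, in an unmarked row. Of 28 neuronal genes, 21 were lower (median −1.09; Fisher's exact test, adjusted p = 1.4e-19; 24 adjusted over the list alone), and without 10 marked rows 11 of 18 were lower (median −1.04; Fisher's exact test, adjusted p = 1.8e-09). Tubb3, in an unmarked row, fell from 48.4 to 23.7 FPKM. Of 15 neurotransmitter and neuropeptide genes, 6 were lower (Fisher's exact test, adjusted p = 0.00045; 9 adjusted over the list alone), and without marked rows 3 of 12 (Th, Dbh and Npy; Fisher's exact test, adjusted p = 0.037). Th fell from 2.97 to 0.574 FPKM and Dbh from 3.29 to 0.447 FPKM, and the sympathetic and spinal list had 3 of 6 members lower (Th, Dbh and Gata3; 3 adjusted over the list alone).

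**Figure D1:**
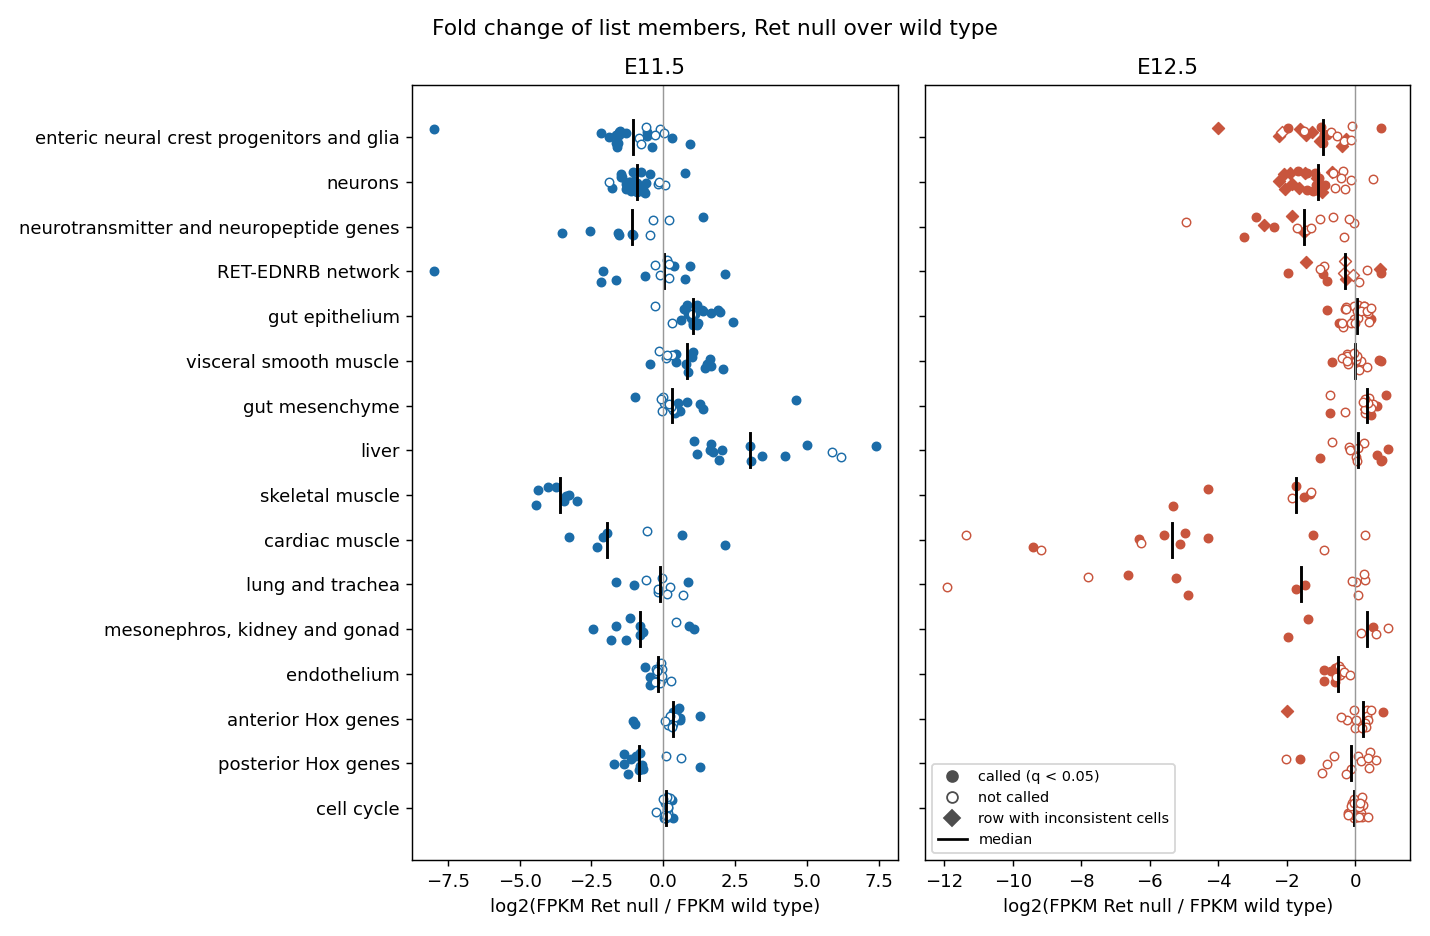
Log2 fold change, Ret null over wild type, of the members of 16 lists at E11.5 (left) and E12.5 (right), with separate horizontal scales. Each point is a gene (filled where called, diamonds for rows whose cells do not follow from one another) and black bars are list medians. The neurons list has its median at −0.91 and −1.09, the cardiac muscle list at −1.97 and −5.34.

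Of the 14 network genes at E12.5, 5 were lower, Ret among them, and 2 higher (8 adjusted over the list alone, not independent evidence as above). Without the 6 in marked rows (Sox10, Ednrb, Gdnf, Gata2, Rarb and Cbl), 3 of 8 were lower and 1 higher (Fisher's exact test for lower members, adjusted p = 0.0128). In unmarked rows, Gfra1 rose from 15.3 to 25.6 FPKM and Gfra2 was lower (values above). Nkx2-5 and Ece1, higher at E11.5, were not called (log2 fold changes −0.92 and 0.12, q = 0.071 and 0.74 in the authors' deposited table). Cbl and Gata2, lower at E11.5, were not called either, both in marked rows. In marked rows, Gdnf was listed at 13.9 FPKM in wild type and 23.3 FPKM in null, and Sox10 at 13.4 and 4.95 FPKM. The row of Ednrb, at 56.3 and 46.9 FPKM, gives p = 0.072 with the smaller q = 0.032 in the authors' deposited table. Of 17 Hirschsprung disease genes, 6 were lower, Ret among them, and 2 higher (12 adjusted over the list alone), and without the marked rows 3 and 1 of 13.

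Gut epithelium genes were called higher in 1 (Shh) and lower in 2 (Cdx1 and Krt19) of 24 members at E12.5, with a median of 0.04 (6 adjusted over the list alone), and smooth muscle genes higher in 2 (Myocd and Synpo2) and lower in 1 (Des) of 16 (3 adjusted over the list alone). Gut mesenchyme genes were higher in 5 of 16 and lower in 1 (Fisher's exact test, adjusted p = 0.00035; 9 adjusted over the list alone), and without the marked row of Pdgfra 4 of 15 were higher, with Barx1 from 26.3 to 49.8 FPKM and Foxf1 from 65.5 to 90.2 FPKM. Hedgehog genes were higher in 3 of 12 (Fisher's exact test, adjusted p = 0.016; 6 adjusted over the list alone), with the receptor gene Ptch1 from 25.1 to 41.8 FPKM and Gli3 from 10.3 to 17.4 FPKM. Genes of intestinal differentiation were lower in 5 of 13 and higher in 1, Lgr5 (Fisher's exact test, adjusted p = 0.0015; 9 adjusted over the list alone), with Tff3, a secretory cell gene, from 88.4 to 23.8 FPKM and the fatty acid binding gene Fabp1 from 34.2 to 12.6 FPKM.

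Markers of neighbouring organs differed beside these groups at E12.5 as well. Of 12 cardiac muscle genes, 7 were lower in the null (median −5.34; Fisher's exact test, adjusted p = 8.98e-06; 9 adjusted over the list alone), with Myh6, the atrial myosin gene, from 31.1 to 0.0459 FPKM and Tnnt2 from 164 to 5.26 FPKM. Of 12 lung and trachea genes, 5 were lower (median −1.59; Fisher's exact test, adjusted p = 0.001; 5 adjusted over the list alone), with Wnt2 from 8.30 to 0.285 FPKM, and Tbx4, a transcription factor gene of lung mesenchyme, fell by 6.63 on the log2 scale. Chosen after their values were seen, the lung surfactant gene Sftpc stood at 174 FPKM in wild type and 0.0449 FPKM in null, with p = 0.13 in the authors' deposited table, and Myl2, a ventricular myosin gene, at 275 and 0.105 FPKM with p = 0.23 in the authors' deposited table. Neither was called. Endothelial genes were lower in 8 of 14 (Fisher's exact test, adjusted p = 2.42e-06; 12 adjusted over the list alone), leukocyte genes in 5 of 15 (7 adjusted over the list alone) and skeletal muscle genes in 5 of 7 (7 adjusted over the list alone).

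The calls of the 2 ages overlapped. Among 12996 genes tested at both, 219 were lower in the null at both ages against 53.9 for independent lists (Fisher's exact test, odds ratio 6.78, p = 3.12e-81), and 64 were higher at both against 15.1 (Fisher's exact test, odds ratio 5.65, p = 9.64e-24). Without marked rows, 152 were lower at both (odds ratio 5.38) and 60 higher (odds ratio 5.51). Opposite calls were frequent too, by a test added after the data were examined: 131 genes against 58.9 for independent lists. Of these, 88 were lower at E11.5 and higher at E12.5 (Fisher's exact test, odds ratio 5.77, p = 4.57e-31), and 43 were higher at E11.5 and lower at E12.5 (Fisher's exact test, odds ratio 1.20, p = 0.26). The ages share no libraries. Genes with large changes in the same direction at both ages included Alb, which rose, and Myh7, Myl4, Ret and Tnnc1, which fell. Apart from Ret, these are liver and muscle genes, of tissues that may have been carried into the dissections. The overlap was not split by tissue or matched on FPKM, so it is not read as a repeat of the effect of Ret loss.

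The difference between the effects at the 2 ages passed the approximate test in 847 of 12852 genes, with the E12.5 effect more negative in 421 and more positive in 426. By list, it passed in 11 of 23 gut epithelium genes, 7 of 16 smooth muscle genes and 8 of 12 liver genes, all with the E12.5 effect the more negative. It also passed in 6 of 13 posterior Hox genes, 5 with the E12.5 effect the more positive and 1 the more negative. It passed in 1 of 17 neuronal genes (Tagln3), 1 of 11 enteric neural crest genes (Hand2) and 1 of 8 network genes (Nkx2-5) outside marked rows.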

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

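All tests of explanations in this part, and the test of the difference between ages, were chosen after the results were seen, and the limits set for the liver list at E12.5 and for Hand2 were reset after their values were seen. The effect of the null genotype differed between E11.5 and E12.5 in 847 genes by the approximate test of the difference itself. The 6 with the smallest p were each called at both ages with opposite signs, which the floor of the deposited p-values favours by construction, so they are not the genes of largest difference. The difference of log2 fold change, E12.5 minus E11.5, was −2.05 for Aldh1a7, 1.84 for Hipk2, −3.16 for Pnliprp1 (a pancreatic lipase-related gene, 1.13 and 3.79 FPKM at E11.5, 253 and 94.1 FPKM at E12.5), 1.89 for Bnc2, −2.38 for the metallothionein gene Mt1 and −2.25 for Sh3bgr, each with adjusted p = 1.68e-05 by the test built on the authors' p-values. The 4 tested Y-linked genes also differed between ages by this test, with Kdm5d at 13.7 and 7.25 FPKM at E11.5 and 9.72 and 12.6 FPKM at E12.5. Xist was higher and these genes lower in the E11.5 null, as a different mix of female and male embryos would give. Their difference between ages is therefore not read as a change in the effect of Ret loss.

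Markers of organs beside the gut differed by genotype, and by different organs at the 2 ages. Skeletal muscle or body wall in the E11.5 wild-type libraries, liver in the E11.5 null libraries and heart in the E12.5 wild-type libraries may account for them, as marker genes outside the lists moved the same way: the median log2 fold change was −1.71 for 15 skeletal muscle genes, 2.04 for 14 liver genes and −3.49 for 17 cardiac genes, each outside 95% of the random lists, which does not tell carried tissue from other causes that change a whole tissue. The most abundant genes stood at 69.4 and 7.17 FPKM (Actc1, E11.5), 4.68 and 148 FPKM (Afp, E11.5) and 378 and 19.2 FPKM (Actc1, E12.5) in wild type and null, and Actc1 is in both muscle lists. An effect of Ret loss was looked at for the liver genes only, and stays open: at E12.5 the liver list had a median of 0.076, but 4 of 12 members were higher, more than among other genes (Fisher's exact test, odds ratio 24.9, adjusted p = 0.0011), and 1 lower. This does not bear on the muscle and heart genes, and neither explanation was tested for the lung genes. At E11.5, anterior Hox genes were higher in 6 and lower in 2 of 14, and posterior Hox genes lower in 11 and higher in 1 of 14. A difference in the stretch of gut sampled was not tested, for these genes or for the neural genes. Sftpc and Myl2, named after their values were seen, were at 0.0966 and 0.242 FPKM in wild type at E11.5 against 174 and 275 FPKM at E12.5. Their E12.5 log2 fold changes of −11.9 and −11.4 were not called.

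Neural crest and neuronal genes were lower in the Ret null at both ages. Spinal cord or brain tissue in the wild-type libraries is not excluded. Olig2, Sox1, Neurog1, Neurog2 and Lhx3 had a highest FPKM of 0.206, so these genes show no such tissue. They were chosen after their values were seen, and other members of their list were not used, so the outcome was known in advance. A smaller share of gut tissue in the E11.5 null libraries is argued against by the gut epithelium list, whose median was 1.04 there. More sympathetic tissue in the wild-type libraries cannot be told apart, since Th, Dbh and Gata3 fell at both ages and are also used by enteric cells or other tissues, while Hand2, also in gut mesenchyme, rose by 0.30 at E11.5 and stood at a log2 fold change of −0.32 at E12.5, not called. Fewer enteric neural crest cells and neurons without Ret stays a hypothesis: the median of 20 neuronal genes outside the lists and marked rows was −0.58 at E12.5, outside 95% of the random lists, which does not tell fewer cells from lower expression per cell.

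The E12.5 table holds 158 tested rows whose cells do not follow from one another, against 1 at E11.5, and 151 of them were called, 139 lower and 12 higher in the null. They were concentrated in the neural lists: 9 of 21 tested enteric neural crest genes, 10 of 28 neuronal genes and 6 of 14 network genes. Marked rows took 0 of 24 gut epithelium, 0 of 16 smooth muscle and 0 of 12 cardiac muscle genes. The fold has more than 6 significant digits in 146 rows, an FPKM in 30, the q-value is below the p-value in 20, and the fold and statistic have opposite signs in 4. That only the fold changes were recomputed is argued against by the median log2 fold per unit of the statistic, 0.89 in the 144 rows with extra digits and p under 0.05 against at most 0.40 in 1000 random sets of unmarked rows matched on FPKM (0.90 over all marked rows, some of which were marked for a small statistic). Cells from another run, or changed after Cuffdiff, stay a candidate explanation: the statistic −4.89 recurs in 19 rows, 18 of them marked and the other that of Ret, whose own cells follow from one another, while no statistic recurs in more than 3 rows at E11.5. Most marked rows with −4.89, that of Sox10 among them, also share p = 0.0088 and q = 0.0035 in the authors' deposited table. A Benjamini-Hochberg q-value cannot lie below its p-value, so these cells do not come from the same adjustment. The statistic 3.00 recurs in 9 other E12.5 rows, that of Gdnf among them. Which it was, and why, was not tested, and no biological explanation was tested.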

How the results depend on the processing

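Settings named here as added were chosen after the data were examined; the others were fixed before. Calls at E11.5 were 1318 at q under 0.01, and with a fold limit of 1 on the log2 scale 606 with no pseudocount, 565 at a pseudocount of 0.1 and 283 at 1. At E12.5 the counts were 516 at q under 0.01, and 423, 414 and 300 under the fold limits. Stricter limits keep fewer genes by construction. At q under 0.1 (2353 and 1497), with an FPKM minimum of 1 (1936 and 1053) and, as added settings, with q recomputed from the deposited p (1956 and 1055) and without marked rows (1955 and 909), total counts stayed within 1.5 times. Besides the fold limits, counts by direction moved further in 4 cases: genes called higher at E12.5 went from 275 to 478 at q under 0.1 and to 93 at q under 0.01, and at q under 0.01 genes called lower at E12.5 went from 785 to 423 and genes called higher at E11.5 from 764 to 499. The share called lower at E12.5, 74.1%, was 68.1% at q under 0.1, 71.1% without marked rows, 82.0% at q under 0.01, and 95.5%, 95.9% and 97.7% under the fold limits. Recentring shifts folds by 0.01 and 0.0013 and a pseudocount keeps the sign of every fold, so neither tests the direction of a call.

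Ret had log2 fold changes, over the pseudocounts and recentring, of −7.97 to −3.24 at E11.5 and −1.95 to −1.61 at E12.5. The number of genes that differed between ages ran from 833 (recentred) to 1173 (no floor on the standard error, added), and was 860 with marked rows (added). The overlap of calls kept its direction and side of the threshold at q under 0.01 and 0.1, with the FPKM minimum and without marked rows. Under the 4 other marking rules (added), 899 to 911 genes were called at E12.5, 847 to 851 differed between ages, and the odds ratios of the overlap of lower genes ran from 5.32 to 5.36; marking Ret too left 4 of 11 enteric neural crest genes lower (Fisher's exact test, adjusted p = 0.0039). Of 62 list medians, 38 lay outside 95% of random lists, and 38 or 39 under the alternatives that keep all 62; without genes that other lists hold, 59 medians could be computed and 37 lay outside. The sympathetic and spinal list at E12.5, without genes that other lists hold, had a median of −0.33 inside that range. Hirschsprung disease genes at E12.5, inside it at 0.12, lay above it at 0.38 without shared genes and at 0.25 without marked rows, and pancreas genes at E12.5, inside it at 0.079, lay above it at 0.20 without shared genes. No paired analysis was possible because each genotype has 1 value per gene, so the replicate numbers reach no column, and the replicate block, leave-one-out of libraries and other splits of the samples were not run for that reason. Depth is unknown, so it sets no limit that can be given here.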

Other observations

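Blood and vessel genes were called as follows at the 2 ages, and the test of the difference between ages passed in 3 of 10 erythroid, 2 of 15 leukocyte and 0 of 14 endothelial genes. At E11.5 the embryonic globin genes Hba-x (1408 to 627 FPKM) and Hbb-bh1 (281 to 96.8 FPKM) were lower in the null, together with Hbb-y, while the red cell transcription factor gene Gata1 was higher (0.906 to 3.12 FPKM), with 4 higher and 3 lower of 10 tested (8 adjusted over the list alone). At E12.5, 5 of 10 were lower, Alas2, a heme synthesis gene, from 62.4 to 9.83 FPKM, and none higher (6 adjusted over the list alone). Of 15 leukocyte genes, 0 were called in the authors' Cuffdiff test at E11.5 and 0 had p under 0.05, and 5 were lower at E12.5, among them Lyz2 from 34.0 to 13.6 FPKM and the complement genes C1qb and C1qc. Of 14 endothelial genes 3 were lower at E11.5 (3 adjusted over the list alone). Glycolysis and hypoxia genes were lower in 6 of 14 at E12.5 (Fisher's exact test, adjusted p = 0.00035; 11 adjusted over the list alone), with Ldha from 664 to 467 FPKM and Pfkp from 17.5 to 6.19 FPKM, and at E11.5 2 were higher and 1 lower (4 adjusted over the list alone). In the same comparisons the cardiac and lung lists fell at E12.5 (medians −5.34 and −1.59) and the liver list rose at E11.5 (median 3.00). Whether carried tissue moved the blood, vessel and glycolysis genes was not tested.

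Retinoic acid genes were higher in 4 and lower in 4 of 16 at E11.5 (9 adjusted over the list alone), with Cyp26a1, which degrades retinoic acid, from 0.369 to 1.67 FPKM and the binding protein gene Crabp1 from 242 to 133 FPKM. At E12.5 they were higher in 3 and lower in 1 of 16 (4 adjusted over the list alone), and Aldh1a2, which makes retinoic acid, was higher at both ages (93.8 to 126 and 42.5 to 64.9 FPKM). MAPK feedback genes were called in 3 of 13 at E11.5 (1 higher, 2 lower) and 2 of 14 at E12.5 (both lower, Dusp6 in a marked row), 3 adjusted over the list alone at each age. Wnt and BMP genes were higher in 1 and lower in 4 of 18 at E11.5 and higher in 2 and lower in 2 at E12.5 (5 adjusted over the list alone at each age), with Lef1 lower at both (6.55 to 3.74 and 2.58 to 1.03 FPKM). Notch genes were higher in 1 and lower in 2 of 15 at E11.5 (4 adjusted over the list alone) and higher in 1 at E12.5 (1 adjusted over the list alone). Of 20 cell cycle genes, 2 were higher at E11.5 (Plk1 and Aurkb; 2 adjusted over the list alone), and 0 were called in the authors' Cuffdiff test at E12.5, where 1 had p under 0.05.

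The remaining lists are given as counts. Mesothelium genes were higher in 3 and lower in 3 of 10 at E11.5 (6 adjusted over the list alone) and higher in 2 and lower in 3 at E12.5 (5 adjusted over the list alone). Intestinal differentiation genes were higher in 2 and lower in 2 of 7 at E11.5, cardiac genes higher in 2 and lower in 4 of 7, and lung genes higher in 1 and lower in 2 of 10 (7, 6 and 3 adjusted over the list alone). At E12.5, liver genes were higher in 4 and lower in 1 of 12 (Fisher's exact test for higher members, odds ratio 24.9, adjusted p = 0.0011; 5 adjusted over the list alone), 1 of 16 pancreas genes was lower (Ins2, which fell by 1.37 on the log2 scale; 1 adjusted over the list alone), mesonephros, kidney and gonad genes were higher in 1 and lower in 2 of 6 (4 adjusted over the list alone), anterior Hox genes higher in 1 and lower in 1 (Hoxd3, in a marked row) of 14 (2 adjusted over the list alone), and 1 of 13 posterior Hox genes was lower (Hoxd13, from 2.58 to 0.854 FPKM; 1 adjusted over the list alone). Sex-linked genes had 0 calls of 4 in the authors' Cuffdiff test at E12.5, where 3 had p under 0.05 (3 adjusted over the list alone). Immediate early and heat shock genes had 0 calls of 10 in that test at E11.5, where 1 had p under 0.05, and 1 of 12 lower at E12.5 (Junb; 3 adjusted over the list alone). The median log2 fold change of this list was 0.11 at E11.5 and −0.36 at E12.5, where it lay outside 95% of the random lists, at percentile 0.21.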
